A study of Homo sapiens with 2 samples.

How the data were processed

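Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on MCF-7 cells, an estrogen receptor positive human breast cancer line, with polyclonal antibodies against UTX. UTX (gene KDM6A) is a demethylase that removes methyl groups from lysine 27 of histone H3. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum, and the libraries were built by random-primed synthesis with tagged primers followed by polymerase amplification. The series holds 2 samples, 1 UTX ChIP library and 1 input library, with 1 replicate per group. A processed file was analysed for 1 of them, the UTX peak list; a signal track, reads or counts of either library were not analysed here, so the sequencing depth is unknown.

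Per the submitters' processing notes, CASAVA, Bowtie2 and MACS were used with the genome build hg19; versions, parameters, the control used in peak calling and any filter after calling are not given in the sources used here. The deposited list gives for each peak its chromosome, start, end, name and a score of the peak caller. The score is the authors' own value, has no header and no stated unit, and was used to rank and filter peaks within this list. It was taken as a numeric scale for medians, for a Pearson correlation of chromosome medians and for an extrapolation below the list. The score never fell below 50. That would be a p of 1e-05 if the score were the negative log10 of p times 10. Neither the labels nor the file state this reading. On 11 chromosomes the last peak lay beyond the last gene of GRCh38, the build of the only gene table at hand. Positions were therefore kept on hg19, and the table was not used to name or place any peak. Starts are given 1-based.

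The peak names carry numbers that rise along the chromosomes with gaps, up to 31753, so the list is part of a longer numbered list. For each chromosome the numbers between its first and last peak were counted to it, and the 172 numbers that fall between 2 chromosomes were split at their middle. The share of numbers present in the list, called the kept share here, was given with a Wilson 95% interval. Each of 23 chromosomes was compared with the whole list by a two-sided permutation test, in which blocks of 50 consecutive numbers were exchanged between chromosomes 20000 times. P-values were adjusted by Benjamini-Hochberg over the 23 chromosomes, at a threshold of 0.05. Chromosome Y, with 5 peaks, was left out of the tests. Peak density was the number of peaks over the distance between the first and the last peak of a chromosome, with an exact Poisson 95% interval. Peaks were also counted by midpoint in 5 Mb windows, and the numbers falling in a window were interpolated between neighbouring peaks. Consecutive numbers kept together were compared with 1000 random draws within chromosomes. Rank correlations were tested with 100000 permutations. Intervals cover counting error only, and all tests describe this 1 list, since no replicate library was analysed.

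Before it was applied, the block permutation test was tested on simulated data of 50 lists with 31753 numbers. The kept share was set to 1.5 times on chromosome 19 and 0.67 times on chromosome 7. Both also passed in the real list, with relative kept shares of 1.48 and 0.847. The test called 100% of these 2 chromosomes and 0.571% of the unchanged ones. It recovered a mean fold of 1.53 for the raised chromosome. Smaller changes, and changes on other chromosomes, were not simulated, so the power for them is unknown. In these lists each number was kept independently of its neighbours. The rate of wrong calls when neighbours are kept together was therefore not tested. An earlier version of the test, which rotated the whole list, was dropped as lacking power on the same simulations, and its values are not given here.

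The tests set before the data were examined included promoter, exon and intron shares, occupancy of 25 gene lists, base composition and 29 sequence motifs. They need an hg19 sequence or annotation and were not run, so no gene is named. The rule set for that case was to name the 10 peaks with the highest score by position. The comparison with the numbering, the grouping of the widest 1% of peaks and the choice of chromosomes and windows described were made after the data were examined. Alternatives set beforehand were the top 50% and top 25% of peaks by score, peaks within 10 kb counted once, and assembled chromosomes only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.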

Results

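To find where UTX is bound in MCF-7 breast cancer cells, 1 UTX ChIP-seq library was collected together with 1 input library. UTX is the histone H3 lysine 27 demethylase encoded by KDM6A. The deposited UTX list held 4556 peaks on chromosomes 1 to 22, X and Y of hg19. Together the peaks covered 4.90 Mb. Peak widths ran from 305 to 10441 bp, with a median of 963 bp (95% interval 951 to 973) and quartiles of 780 and 1207 bp. The authors' peak scores ran from 50 to 871.07, with a median of 60.06 (95% interval 59.58 to 60.54), and 493 peaks reached 100 or more. There was no replicate of either library, and the read depth behind the peaks is unknown.

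The 10 strongest UTX peaks lay on 9 chromosomes, and 7 of them were narrower than 1000 bp. The highest score, 871.07, belonged to a 782 bp peak on chromosome 11 from 1817615 to 1818396. It was followed by a peak on chromosome 2 from 11638499 to 11639326 with a score of 785.95, and by a peak on chromosome 1 from 7507692 to 7508565 with a score of 757.59. The fourth and the fifth were wider, with 1882 bp on chromosome 3 from 192315225 to 192317106 (score 612.32) and 1561 bp on chromosome 8 from 125149841 to 125151401 (score 522.67). A second peak of chromosome 1, from 112055701 to 112056663, scored 495.66. Chromosome 15 held the widest of the 10, with 2336 bp from 96437158 to 96439493 and a score of 422.25. The remaining 3 lay on chromosome 14 from 77866296 to 77867041 (score 403.1), on chromosome 21 from 43796274 to 43797009 (score 400.18) and on chromosome 12 from 2904914 to 2905808 (score 372.13). Each of these scores was above the 99th percentile of the list, 222. The genes around these positions were not analysed here.

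Wider peaks tended to score higher. Across peaks, which are not independent replicates, width and score were correlated with a Spearman rho of 0.31 (permutation p = 1e-05, the smallest that 100000 permutations can give). The median score rose from 55.85 in the narrowest 25% of peaks (305 to 780 bp) to 57.82, 61.95 and 68.76 in the following quartile groups. The extremes did not coincide: of the 46 peaks with the highest scores and the 46 widest peaks, 2 were shared. The 46 highest-scoring peaks had a median width of 1211.5 bp, whereas the 46 widest, all of 3327 bp or more, had a median score of 69.96.

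**Figure D1:**
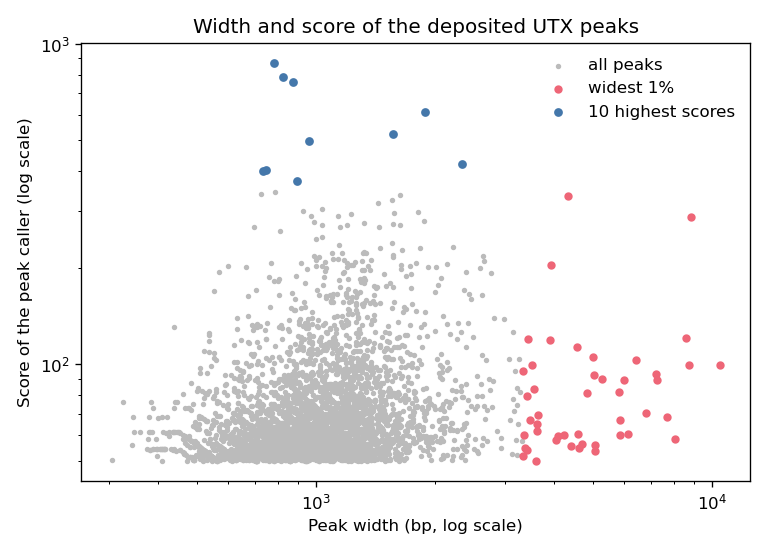
Width of each deposited UTX peak in bp (x axis, log scale) against the authors' peak score (y axis, log scale). Grey points are all 4556 peaks, blue points the 10 highest scores and red points the 46 widest peaks; the highest scores sit at widths between 736 and 2336 bp, apart from the widest peaks.

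UTX peaks were spread unevenly over the chromosomes. Between the first and the last peak of each chromosome, with chromosome Y left out, the density was highest on chromosome 14, with 259 peaks or 2.95 per Mb (95% interval 2.60 to 3.33), and lowest on chromosome 18, with 26 peaks or 0.339 per Mb (0.221 to 0.496). Chromosomes 3, 19 and 8 followed chromosome 14 with 2.24 (2.04 to 2.46), 2.20 (1.84 to 2.62) and 2.13 (1.90 to 2.38) peaks per Mb. Chromosomes X, 13 and 4 were next above chromosome 18, with 0.725 (0.596 to 0.875), 0.756 (0.590 to 0.953) and 0.810 (0.687 to 0.949) peaks per Mb. Chromosome 13 ranked above chromosome 4 once the longest interval without a peak was left out of each length (0.654 against 0.517, relative to all chromosomes). That interval is defined by the peaks, so leaving it out raises the density of a chromosome by construction. The median over the 23 chromosomes was 1.63 per Mb. Chromosome Y held 5 peaks, all between 13445321 and 13843379, a stretch too short to set its density beside the others. No reads were analysed, so whether the DNA behind these peaks came from chromosome Y was not tested. The 5 peaks are therefore not read as UTX binding on that chromosome. Peaks clustered along chromosomes, so the Poisson intervals, which treat peaks as independent, are too narrow; no input track was used to relate these densities to DNA content. Among the top 25% of peaks by score, the density of chromosome 19 relative to all chromosomes was 2.17, against 1.41 with all peaks, which placed it above chromosome 14 (1.90); chromosome 18 stayed lowest (0.268).

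Within chromosomes, the peaks also formed dense stretches. Of 604 windows of 5 Mb, the median held 6 peaks (quartiles 3 and 11), 36 held none, and the variance was 4.33 times the mean. Assembly gaps were not excluded and windows at chromosome ends can be partial, so both may add to the empty windows and the variance. The densest window, on chromosome 3 from 160000001 to 165000000, held 37 peaks (Poisson 95% interval 26.1 to 51.0). The next was on chromosome 8 from 110000001 to 115000000 with 34 peaks (23.5 to 47.5). Of the 9 windows with 24 or more peaks, chromosomes 3 and 8 held 3 each. On chromosome 8 the others held 29 peaks from 85000001 to 90000000 and 24 from 105000001 to 110000000, and on chromosome 3 they held 24 peaks from 145000001 to 150000000 and 24 from 165000001 to 170000000. Chromosome 14 from 40000001 to 45000000 held 28 peaks, and chromosome 1 held 27 from 195000001 to 200000000 and 26 from 215000001 to 220000000. On chromosome 1 the 248 peaks beyond its longest interval without a peak (120792069 to 142568758) lay at 2.38 per Mb (2.09 to 2.70). The 153 peaks before that interval lay at 1.27 per Mb (1.08 to 1.49). How much of the interval is assembled sequence was not examined. Neighbouring peaks were a median of 297 kb apart, and 178 of 4532 neighbouring pairs (3.93%) were closer than 10 kb.

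**Figure D2:**
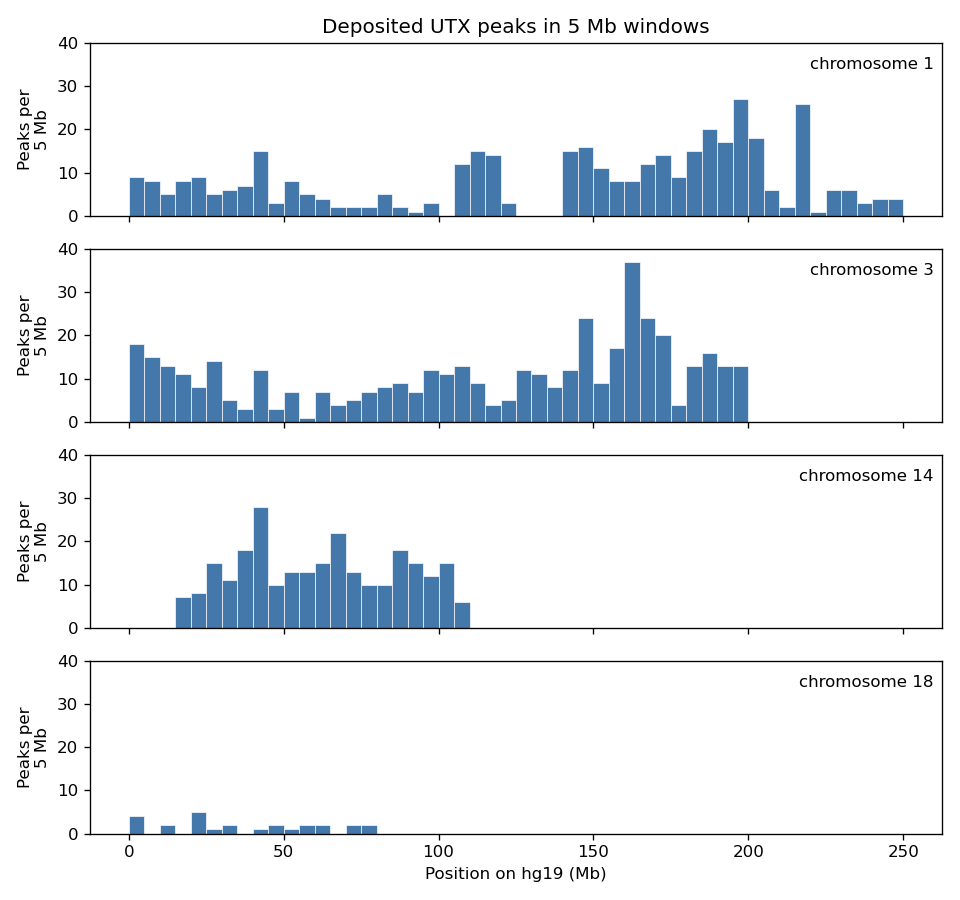
Deposited UTX peaks per 5 Mb window (y axis, number of peaks) along chromosomes 1, 3, 14 and 18 (x axis, hg19 position in Mb), 1 bar per window. Chromosome 3 reaches 37 peaks in 1 window, while all of chromosome 18 holds 26.

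The peak numbers made it possible to see how much of each chromosome's original list was deposited. The list held 14.3% of the 31753 numbers, and the kept share was higher on chromosome 19 (21.2%, Wilson 95% interval 18.2 to 24.7), chromosome 20 (18.9%, 15.9 to 22.2), chromosome 17 (18.4%, 15.7 to 21.4) and chromosome 1 (17.8%, 16.2 to 19.4). It was lower on chromosome 7 (12.1%, 10.9 to 13.5) and chromosome 2 (12.4%, 11.3 to 13.6). In the block permutation test these 6 of 23 chromosomes passed the threshold, with adjusted permutation p of 0.0017 for chromosomes 19 and 1 and 0.035 for chromosomes 20, 17, 7 and 2. Chromosome 21 had a share of 20.1% (16.01 to 24.8) and did not pass (adjusted permutation p = 0.065). Neither did chromosome 18, with 11.4% (7.87 to 16.1; adjusted permutation p = 0.37), nor chromosome 14, with 15.7% (14.004 to 17.5; adjusted permutation p = 0.31). Among the top 50% of the peaks by score, chromosomes 1, 2 and 7 no longer passed (adjusted permutation p = 0.054 for each), although their kept shares relative to the list were 1.23, 0.810 and 0.783, against 1.24, 0.863 and 0.847 with all peaks. There, chromosomes 11 and 21 passed as higher and chromosome 5 as lower (adjusted permutation p of 0.039, 0.039 and 0.014). In the top 25%, chromosomes 2, 7 and 20 did not pass (adjusted permutation p of 0.076, 0.082 and 0.12), with relative kept shares of 0.737, 0.719 and 1.495, farther from 1 than with all peaks (1.31 for chromosome 20). The relative kept share of chromosome 19 there was 2.27, against 1.48 with all peaks.

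**Figure D3:**
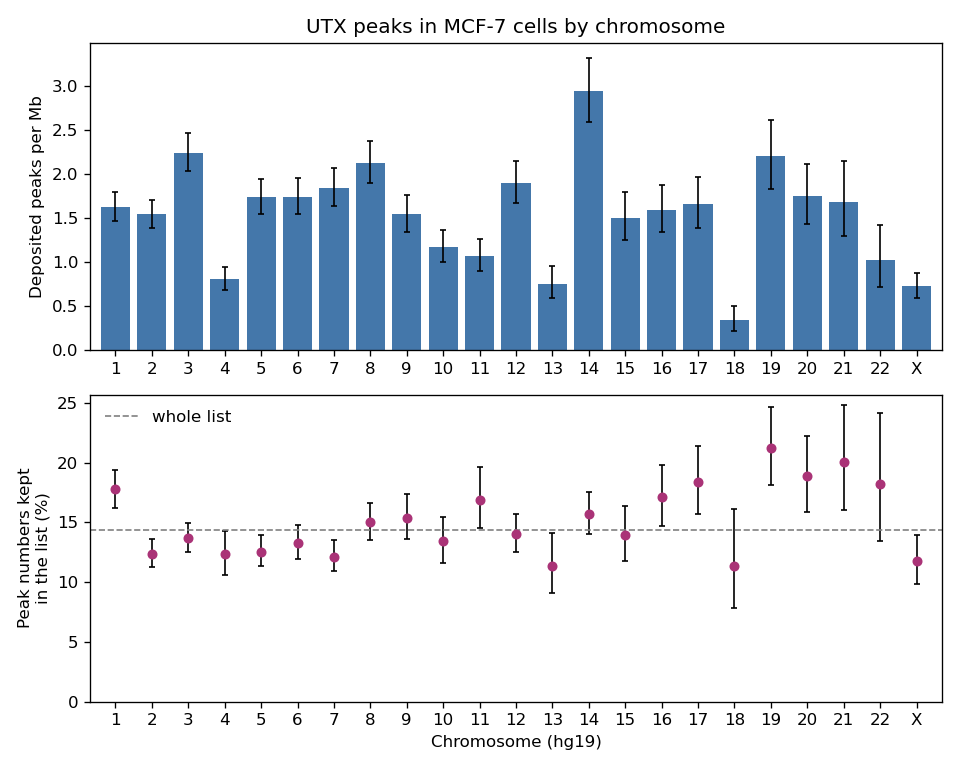
Upper panel, deposited UTX peaks per Mb between the first and the last peak of chromosomes 1 to 22 and X (chromosome Y not drawn), as bars with exact Poisson 95% intervals; lower panel, percent of the peak numbers of each of these chromosomes that are in the deposited list, as points with Wilson 95% intervals and a dashed line at the 14.3% of the whole list. Among those drawn, chromosome 14 is highest and chromosome 18 lowest in density, while chromosome 19 has the largest kept share.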

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

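The densities of chromosomes 14 and 18 relative to all chromosomes, 1.89 and 0.217, stayed within their counting intervals among the top 50% and top 25% of peaks by score, with peaks within 10 kb counted once, and with the longest interval free of peaks left out of the length. The number of chromosomes whose kept share differed was 6 with all peaks, 6 in the top 50% with 3 in common, and 3 in the top 25%, all 3 in common. The median width rose from 963 bp to 1059 bp in the top 50% and 1137 bp in the top 25%, as the correlation of width and score entails. On chromosome 1 the density after its longest free interval was 1.87 times that before it and 1.35 times in the top 25%; the cause was not tested. Consecutive numbers were kept together 1.10 times as often as in random draws (permutation p = 0.002), 1.31 times in the top 50% and 1.88 times in the top 25%. Once peaks within 10 kb were counted once, the direction reversed to 0.900 times (553 pairs against 614 expected, permutation p = 0.003). That alternative by construction removes 1 member of the closest pairs. The other values were counted per chromosome and alternative. In 6 of these cases, all on chromosomes 1, 2, 7 and 20, a kept share no longer passed. Those of chromosomes 17 and 19 passed under every alternative. In 4 cases a density left its counting interval, and in 32 a value kept its call or stayed within that interval. Those that moved include the relative density of chromosome 19, from 1.41 to 2.17 in the top 25%, and of chromosome 3, from 1.44 to 1.12. That of chromosome 13 went from 0.485 to 0.654 without its longest interval free of peaks, of 29.7 Mb, which placed it above chromosome 4 (0.517). Leaving out an interval defined by the peaks raises the density by construction. Kept shares that still passed moved too: in the top 25% that of chromosome 19 relative to the list went from 1.48 to 2.27, and that of chromosome 17 from 1.28 to 1.70. The length of chromosomes without gaps, and each alternative for promoters, gene lists, base composition and motifs, could not be run without an hg19 sequence. The choice of assembled chromosomes removed no peak and tests nothing. No paired analysis was possible because each group has 1 library and 1 of them has a peak list. Replicates could not be left out for the same reason. The unknown depth limits what a missing peak can say.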

Other observations

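All tests in this part were chosen after the results they examine had been seen. The widest UTX peaks lay together in a few regions. Of the 46 widest peaks, 38 had another of them within 5 Mb, against a mean of 8.30 and a highest value of 25 among 2000 random sets of peaks (permutation p = 0.0005, the smallest these draws can give). The ratio to the random sets was 4.58, and with distances of 1 Mb and 20 Mb it was 16.6 and 1.73. The largest group, 11 of the 46, lay on chromosome 1 from 142568759 to 148679369, next to the longest interval of that chromosome without a peak, and included the widest peak of the list, 10441 bp from 148274612 to 148285052. Chromosome 2 held 6 from 89866834 to 91742038, and chromosome 3 held 6 from 62477380 to 63366388. On chromosome 3 these 6 were all the peaks of the stretch, with a median width of 4542.5 bp.

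Wider peaks score higher, so score was held fixed in a further comparison. Among 2000 random sets of 46 peaks matched to the widest ones on score, in 20 score bins, a mean of 8.27 and at most 20 peaks had another within 5 Mb, against the observed 38, which argues against score as the reason for the grouping. Repeated sequence or raised copy number may be a source of the 9 regions that hold the 38 grouped peaks, since MCF-7 cells are known to carry extra DNA copies in several regions. No input, copy number track or sequence was analysed, so these cannot be told apart from each other or from broad UTX binding, which was not tested.

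Chromosome 18 was poor in peaks in the longer numbered list too. Its numbered peaks lay at 2.98 per Mb, against a median of 9.34 over the chromosomes, and the numbers fell from 4.80 per Mb in the first 35 Mb to 1.46 per Mb in the rest, a division chosen from the counts. The deposited peaks in these parts, 14 and 12, lay at 0.4003 and 0.287 per Mb, a ratio of 1.40 (95% counting interval 0.645 to 3.02) beside 3.29 (2.46 to 4.41) for the numbers, and the difference between the ratios was not tested. Selection after the peaks were numbered cannot by itself account for the low density. The kept share was 0.791 of that of the whole list, so such selection would account for a part at most. The density was 0.217 of that of all chromosomes (95% interval 0.142 to 0.318, which treats peaks as independent). Fewer copies of chromosome 18, or of part of it, in this MCF-7 stock may lower the number of detectable peaks. The median score on the chromosome, 61.19 (95% interval 55.87 to 74.72), spans the 60.06 of all peaks and does not decide, and no input track was analysed. Fewer UTX sites on this chromosome remain open too, as untested.

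How 4556 of 31753 numbered peaks were chosen is not given in the sources used here. Selection by score is a candidate explanation: across the 23 chromosomes, the median score of the deposited peaks and the kept share were correlated, with a Spearman rho of 0.505 (95% bootstrap interval 0.0334 to 0.798; permutation p = 0.015, adjusted p = 0.03 over 2 relations) and a Pearson r of 0.714 (permutation p = 0.00015), which was 0.610 without the 2 chromosomes farthest from the median score. The density of numbered peaks had no such relation to the kept share (rho 0.0168, Pearson r -0.0723, adjusted permutation p = 0.94). Near the floor the list was still rising, with 621 peaks scoring from 50 to under 52 and 536 from 52 to under 54. The log number of peaks at or above a score was continued downwards with its slope between 50 and 55. It would reach all numbered peaks at a score of 23.5 (95% bootstrap interval 22.1 to 24.9). This takes that slope as constant and all absent numbers as scoring below 50, and the interval covers resampling only. Whether 50 was the peak caller's own limit or a later filter is unknown. If it was the caller's limit, no numbered peak would score below 50 and the value of 23.5 would not apply. The rise near the floor therefore does not decide for selection by score. The 733 consecutive pairs kept were 1.10 times the 667 of random draws within chromosomes, and the highest draw gave 721. This argues against a choice with an equal chance for every number of a chromosome. A choice peak by peak whose chance varies by region, also one by score, could give an excess too and was not tested. The ratio of pairs kept to pairs drawn was 1.31 and 1.88 among the top 50% and 25% by score. With peaks within 10 kb counted once it reversed to 0.900 (553 pairs against 614 expected, permutation p = 0.003). That step removes by construction 1 member of the closest pairs, so whether the excess holds beyond 10 kb is not decided.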
